A study of Homo sapiens with 8 samples.

How the data were processed

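Gene expression was measured in the human prostate cancer cell line 22Rv1 and in cells derived from it by growth in animals. Total RNA was purified on columns, checked on a bioanalyser, converted to biotin-labelled cRNA and hybridised to 8 single-colour Illumina bead arrays, per the labels' protocols. The 8 arrays fell into 4 groups of 2, per the labels: the parental line carrying a luciferase label, a primary tumour derivative, and the metastatic derivatives M3-1 and M3-2. The meaning of "M3", the site of each metastasis and the number of animals are not given in the sources used here. Nothing in the labels says that the 2 arrays of a group came from separate cultures or animals. P-values therefore measure only the spread between these arrays, which may be technical, and comparisons of the metastatic lines carry the spread within a line, not between lines.

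The authors deposited a table of log2 intensities for 47320 probes, which was used for all results. The software, background correction and normalization behind it are not given in the sources used here. From the values, the authors' arrays share the same distribution, since the largest spread between arrays at any rank was 0.012 on the log2 scale, as after quantile normalization. The lowest value on every array was 5.32, the median was 6.40 and the highest 15.1, so no background had been subtracted down to zero. Folds of dim genes are therefore understated. A second deposited table of signals without normalization was not used. Its 16 columns of per-sample values carry running numbers that match no sample's labels, and a match by order or by values was not made.

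The plan fixed before the data were examined had named Illumina background correction with control probes (neqc) and detection p-values, both of which need that second table. The deposited log2 values took their place, and the detection filter was rebuilt from them. The background level was taken as the mode of all values, 6.12, with an SD of 0.183 from the values below it. A probe counted as above background where it exceeded 6.55, the level that a share of 0.01 of such a background would exceed, on at least 2 arrays. About 43.1% of the probes lay above this level on each array. Probes were named through GEO's platform annotation, which gave 1 gene symbol for 30112 probes, several for 8 and no listed gene for 17200. Symbols were compared with current ones through Entrez identifiers, and 0 changed. Where a gene had several probes above background, the brightest on average was used, which left 12291 genes from 16731 probes. Among the 113 genes taken by the naming rule described below, 39 had several probes above background. In 37 of these all such probes moved in the same direction between parental and metastatic cells, the only comparison checked. The exceptions were RTN1 and ZMAT3. Genes named outside the rule were not checked.

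Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 4 group means was fitted to all 8 arrays (lmFit), followed by empirical Bayes moderation (eBayes), with 4 residual degrees of freedom per gene and 9.38 more from the prior. Metastatic lines were compared as the mean of M3-1 and M3-2, each with equal weight. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p below 0.05 are called changed. Differences are given on the log2 scale, with a standard error for the leading genes, or as folds. Folds are 2 to the power of the log2 difference. Where a gene was at or below 6.55 on every array of a group, that group has only a bound, and the fold is given as "at least", computed against the level of 6.55. Where this held for 1 of the metastatic lines, its arrays were set to that level in the mean of both lines.

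Gene lists were fixed before the data were examined. There were 26 lists holding 591 symbols, of which 558 were on the array. They covered hormone response and steroid metabolism, cell identity, growth, stress, metabolism, immune and signalling pathways, and markers of other cell types. The 23 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Called members are also counted with p-values adjusted over the list alone. None of the 28 list calls held when camera estimated the correlation from the data, and that adjusted p is given beside each call.

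Named genes followed a rule fixed in advance. From each of 4 comparisons it took the 8 largest changes in each direction among called genes whose arrays did not overlap between the sides, leaving out provisional LOC symbols. For the metastatic comparisons the gene also had to be called in the same direction in each line. The rule added the 3 members with the largest change from each called list, the 8 highest and 8 lowest genes of the set that separated both metastatic lines from both other groups, and a fixed set of prostate and cell-state genes, of which CDH1, VIM and MKI67 passed the background filter and KLK3 did not. Genes outside the rule are given only as members of the fixed lists or where the text says that they were chosen after their values were seen.

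The tests were tried on simulated arrays with the real means and the real spread of each group, in which 200 of 12291 genes were changed. Each comparison was simulated once, with fewer changed genes than real calls. The shares below therefore need not hold for the real counts. Genes changed by 1 on the log2 scale were recovered in 100% of cases for the primary tumour against parental cells and for the metastatic lines against either group, and in 98% for M3-2 against M3-1. At 0.5 the shares were 40%, 46%, 58% and 28% for the primary tumour against parental cells, the metastatic lines against parental cells, the metastatic lines against the primary tumour, and M3-2 against M3-1. False calls numbered 30 of 200 calls for the primary tumour against parental cells and 36 of 209 for the metastatic lines against parental cells, above the nominal share. They numbered 0 of 179 for the metastatic lines against the primary tumour and 0 of 163 for M3-2 against M3-1. The parental arrays were simulated with their wider spread, which may explain the excess, but a simulation with equal spreads was not run. A simulated list of genes all shifted the same way was recovered in each comparison. Its genes varied independently, so this does not show how the set test behaves where genes are correlated.

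Alternatives covered the background filter, the choice of probe, the moderation, array weights, the threshold, the arrays in the fit, the replicate number as a block, each array left out in turn, the set test, and, chosen after seeing the data, a normexp background correction, cyclic loess normalization and a filter on mean intensity. Overlaps between comparisons that share control arrays were set beside 100 simulations of unchanged groups and, chosen after seeing the data, beside overlaps with a different parental array for each comparison. No comparison had 3 arrays in every group, so regroupings of the arrays were not counted. The number of arrays limits the precision of every value. No genome build was needed, and no coordinates are given.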

Results

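Expression profiles were compared between 22Rv1, an androgen-responsive human prostate carcinoma line, and cells recovered after its propagation in animals. The groups were the luciferase-labelled parental line, a primary tumour derivative and the metastatic derivatives M3-1 and M3-2, each with 2 arrays. After filtering, 12291 genes were above background. Arrays of a group were closely alike, with correlations across genes of 0.987 in parental cells, 0.995 in the primary tumour, 0.997 in M3-1 and 0.993 in M3-2. The spread between the parental arrays was the widest, with an SD of 0.22 on the log2 scale, against 0.14 in the primary tumour, 0.10 in M3-1 and 0.16 in M3-2. The root mean square difference between group means was smallest between the metastatic lines, at 0.24, and was 0.31 between parental cells and the primary tumour. It was 0.37 between parental cells and M3-1 and 0.39 between parental cells and M3-2.

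The primary tumour derivative was compared with the parental line to see what differed in cells that had grown as a tumour. FABP7, a fatty acid-binding protein, was at least 12.1-fold higher in the primary tumour, with a mean log2 intensity of 10.15 ± 0.23 (SD, n = 2) against 6.21 ± 0.12 (n = 2) in parental cells, where it was not above background. The calcium-binding protein gene S100P was 9.33-fold higher, with a log2 difference of 3.22 (SE 0.12, adjusted p = 4.48e-09). EFEMP1, which encodes the matrix glycoprotein fibulin-3, was higher by a log2 difference of 3.0 (SE 0.14), and NQO1, a quinone reductase, was 7.56-fold higher. IGFBP3, a secreted binding protein for insulin-like growth factors, showed the largest decrease. Its mean log2 intensity fell from 12.72 ± 0.28 (n = 2) to 8.18 ± 0.04 (n = 2), a 23.2-fold difference (adjusted p = 4.30e-09).

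The other large increases in the primary tumour were in RASL11B, a small GTPase of the Ras family (at least 6.06-fold), the cytochrome P450 gene CYP4X1 (at least 5.11-fold), the transcription factor FOXA3 (6.03-fold) and PPP1R1B, a phosphatase inhibitor (5.96-fold). The tight junction gene CLDN11 was 7.36-fold lower, COLCA1 at least 4.97-fold lower, PNMA2 4.93-fold lower and CFC1, a co-receptor for Nodal signalling, 3.98-fold lower. CRIP1 and HGF, the ligand of the MET receptor, were 3.91-fold and 3.50-fold lower. The highest adjusted p among these was 2.67e-06, that of HGF. In total 845 of 12291 genes changed by the limma test, 420 higher and 425 lower, and 164 of them changed at least 2-fold. In the single simulation of this comparison, with 200 genes changed, 30 of 200 calls were false. Genes near the threshold are therefore less certain than the nominal rate implies, though the false share among the real calls may differ. The count was 354 without primary tumour replicate 1, 387 without primary tumour replicate 2, 1395 without parental replicate 1, and 419 when only the 4 arrays compared entered the fit.

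Neuroendocrine genes were lower in the primary tumour. Of 16 measured members, 8 fell, none rose and 8 did not pass, or 10 lower and 1 higher when adjusted over the list alone. SNAP25, a component of the vesicle fusion machinery, fell by 1.36 on the log2 scale (SE 0.13), the granule protein gene CHGB by 1.33 (SE 0.12), and the RNA-binding protein gene CELF3 by 1.09 (SE 0.15). Camera gave this list an adjusted p of 2.6e-05, and an adjusted p of 0.112 with an estimated correlation. Genes of steroid and androgen metabolism were also lower, with 6 of 16 members lower and 0 higher, or 7 lower adjusted over the list alone. The decreases were in UGT2B11, UGT2B17 and UGT2B15, which encode enzymes that conjugate steroids with glucuronic acid (3.42-fold, 2.93-fold and 2.67-fold), and in UGT2B28, AKR1C2 and AKR1C4. The UGT2B genes are near-identical in sequence, as are the AKR1C genes, so probes may not separate their members. Camera gave the list an adjusted p of 0.000717, and an adjusted p of 0.112 with an estimated correlation.

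Epithelial genes moved the other way. Of 21 measured members, 7 rose and none fell, or 8 higher adjusted over the list alone. The keratin genes KRT19 and KRT18 were 2.68-fold and 1.81-fold higher, and the mucin gene MUC1 was 2.14-fold higher. The list's adjusted p was 5.24e-05, and 0.131 with an estimated correlation. In the mesenchymal list 3 of 12 members were lower and 1 higher, or 4 lower and 2 higher adjusted over the list alone. N-cadherin (CDH2) fell by 1.28 (SE 0.12), tenascin C (TNC) by 0.91 (SE 0.13) and CCN2, a matricellular protein gene, by 0.70 (SE 0.13), while S100A4 was at least 1.63-fold higher, being below background in parental cells. This list had an adjusted p of 0.0422, and an adjusted p of 0.193 with an estimated correlation. Its call ended in 7 of 17 other settings, with adjusted p-values from 0.0126 to 0.120. They included each fit without 1 array of either group: 0.0739 and 0.0972 without parental replicates 1 and 2, and 0.0544 and 0.0676 without primary tumour replicates 1 and 2.

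The TGF-beta and BMP list was lower in the primary tumour, with 4 of 14 members lower and none higher, or 7 lower and 1 higher adjusted over the list alone. BMP2 fell by 1.35 (SE 0.13), GDF15 by 1.12 (SE 0.13) and ID4 by 0.74 (SE 0.18). The adjusted p was 0.000115, and 0.112 with an estimated correlation. In cholesterol synthesis 2 of 18 members, HMGCS1 and LSS, were lower, by 0.66 (SE 0.16) and 0.62 (SE 0.15), with the same count adjusted over the list alone. IDI1, the third gene named from this list, had a log2 difference of -0.40 and did not pass. The adjusted p of this list was 0.0138, 0.150 with an estimated correlation, and 0.0676 without primary tumour replicate 2. The cancer-testis list was called upward (adjusted p = 0.0422, and 0.193 with an estimated correlation), although 0 of its 14 members rose and 1, GAGE12F, fell, or 2 higher and 1 lower adjusted over the list alone. Its leading genes MAGEA12, MAGEC2 and MAGEA1 differed by 0.50, 0.36 and 0.34 without passing, MAGEC2 being below background on both parental arrays and 1 of the 2 primary tumour arrays. The list's call ended in 7 of 17 other settings (adjusted p from 0.0164 to 0.151): 0.0614 and 0.151 without parental replicates 1 and 2, 0.0544 and 0.0676 without primary tumour replicates 1 and 2, and also without the filter, with the mean of probes and with array weights. MAGEA12 passed in 2 of 18 settings (0.0167 to 0.447), MAGEA1 in 1 (0.0367 to 0.597) and MAGEC2 in 1 (0.0182 to 0.407). Calls of CCN2, HMGCS1, LSS and ID4 ended when single arrays were left out, at the most with an adjusted p of 0.180 for LSS without primary tumour replicate 2. LSS also lost its call with the mean of its probes, where it fell by 0.36 (adjusted p = 0.110), with array weights (0.0545) and with only the groups compared (0.0897), as did HMGCS1 in the last of these (0.0959). Over 18 settings the adjusted p ran from 0.00349 to 0.180 for LSS and from 0.000631 to 0.165 for HMGCS1.

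The comparison of the metastatic lines with the parental line is the one the study's design names. LUM, which encodes the collagen-binding proteoglycan lumican, was 24.4-fold higher in the metastatic lines, rising from a mean log2 intensity of 6.88 ± 0.46 (SD, n = 2) to 11.49 ± 0.29 (n = 4, both lines). NQO1 rose from 9.11 ± 0.0088 (n = 2) to 13.45 ± 0.06 (n = 4), a 20.2-fold difference (adjusted p = 1.88e-11). LGALS4, a galectin of the gut epithelium, was 17.5-fold higher and SPOCK2, a matrix proteoglycan gene, 14.4-fold higher. IGFBP3 was 38.8-fold lower, with a log2 difference of -5.28 (SE 0.14, adjusted p = 4.32e-11).

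**Figure D1:**
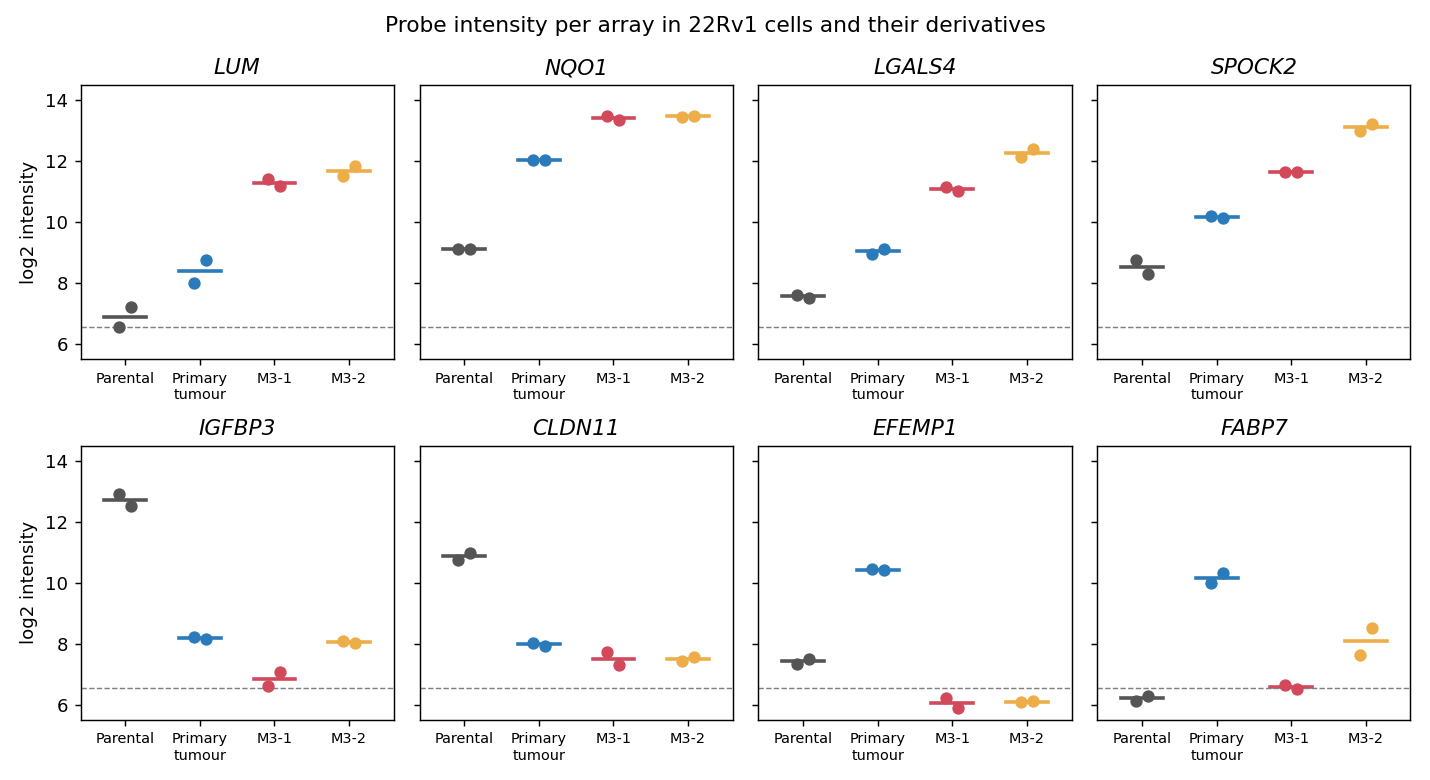
Log2 probe intensity (vertical axis) of 8 genes in parental cells, the primary tumour and the metastatic lines M3-1 and M3-2, with 1 point per array and a bar at the group mean. The dashed line is the background level of 6.55; LUM, NQO1, LGALS4 and SPOCK2 were lowest in parental cells, intermediate in the primary tumour and highest in the metastatic lines, while EFEMP1 lay at background on all 4 metastatic arrays.

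Further genes were higher in the metastatic lines than in parental cells in each line separately. These were S100P (log2 difference 3.46, SE 0.11), the purinergic receptor gene P2RY1 (8.83-fold), PPP1R1B (7.24-fold) and PLA2G4C, a phospholipase (6.90-fold). CLDN11 was 10.3-fold lower, ANGPTL4, an inhibitor of lipoprotein lipase, 9.40-fold lower, CRIP1 9.29-fold lower and the neuropeptide gene NMB 8.85-fold lower. CFC1 was at least 7.13-fold lower and was not above background on any of the 4 metastatic arrays. The adenosine deaminase gene ADA2 was 6.49-fold lower, and the alpha-globin gene HBA2 6.78-fold lower. Sequences of HBA2 and HBA1 are near-identical, and HBA1, below background in M3-1, was at least 4.56-fold lower. The highest adjusted p among the genes named in this paragraph was 1.06e-08, that of HBA1, which was not among the genes taken by the naming rule.

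Across the 12291 genes, 1687 changed between the metastatic lines and parental cells, 780 higher and 907 lower, and 299 of these changed at least 2-fold. Each line on its own gave 1219 changed genes for M3-1 (544 higher, 675 lower) and 1497 for M3-2 (723 higher, 774 lower). In both lines 378 genes were higher and 492 lower than in parental cells, and 7 genes were called in opposite directions. Independent lists of these sizes would share 32.0 and 42.5 genes. Simulated unchanged groups with the same controls shared 0.01 on average and at most 1. Only 0.12 genes for M3-1 and 0.75 for M3-2 were called in them on average, so little overlap was possible. The simulation thus cannot show how much overlap shared controls give among lists of the real sizes. The primary tumour and the metastatic lines shared 215 higher and 263 lower genes against parental cells, with 27 in opposite directions. Independent lists would share 26.7 and 31.4. The simulation gave 0.11 on average, with the same limit, since it called only 0.21 genes for the primary tumour and 0.82 for the metastatic lines. With a different parental array as the control of each line, a test chosen after seeing the data, 323 genes were higher and 439 lower in both lines in one assignment and 313 and 438 in the other, with 27 opposite in each. Independent lists would share 52.3 and 65.1, and 53.7 and 76.4. The same split for the primary tumour and the metastatic lines gave 195 higher and 247 lower with 54 opposite, and 188 and 228 with 89 opposite, where independent lists would share 41.2 and 48.6, and 55.4 and 61.6. Each control was then a single array assumed to vary like the other groups, although the parental arrays varied more, so part of each excess may still come from the controls. Weighting the arrays by their spread, which gave the parental arrays the lowest weight, left 1089 genes changed in the metastatic lines. The count for both lines together was 1106 without M3-1 replicate 1 and 1099 without M3-1 replicate 2. For M3-1 alone it was 574 and 572 without these arrays, and for M3-2 alone it was 927 without M3-2 replicate 1 and 994 when only the arrays compared entered the fit. In the single simulation of the combined comparison 36 of 209 calls were false, a share that may differ among the real calls.

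**Figure D2:**
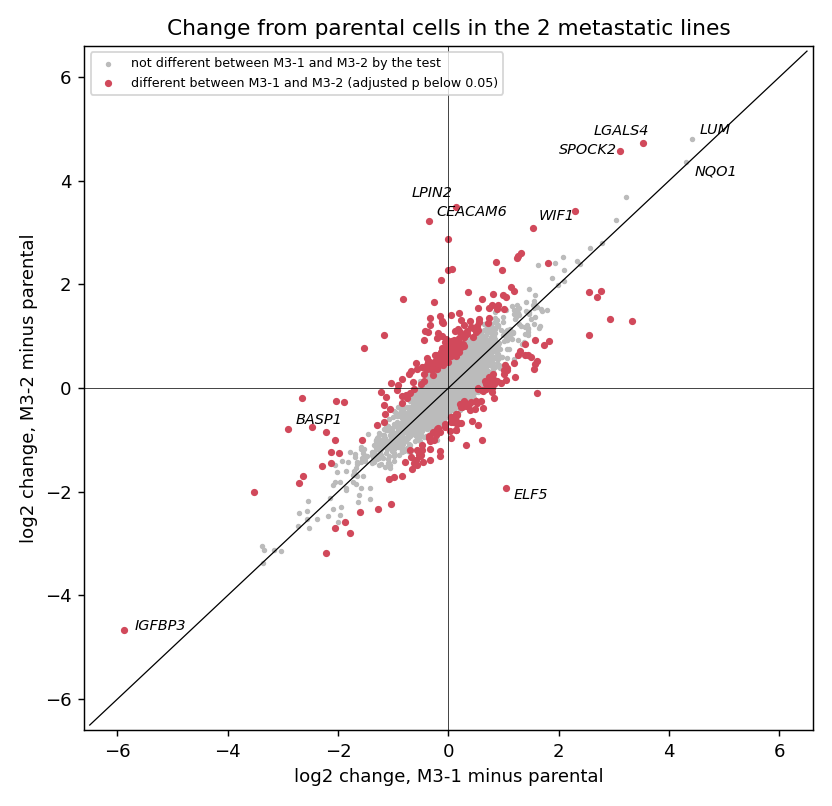
Log2 change from parental cells in M3-1 (horizontal axis) and in M3-2 (vertical axis), with 1 point for each of the 12291 genes and the line of equal change. Red points are the 303 genes that differed between M3-1 and M3-2 by the limma test; LUM and NQO1 lie near the line of equal change, whereas LPIN2 and CEACAM6 were raised in M3-2 alone among the metastatic lines.

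Neuroendocrine genes were lower in the metastatic lines than in parental cells, with the lowest p of the 23 lists tested in this comparison. Of 16 members, 10 fell and none rose, or 11 lower adjusted over the list alone. CHGB was at least 3.58-fold lower, being below background in M3-1. SNAP25 fell by 1.73 (SE 0.11), CELF3 by 1.51 (SE 0.13) and synaptophysin (SYP) by 0.98. The adjusted p was 2.33e-09, and 0.0521 with an estimated correlation. In steroid and androgen metabolism 5 of 16 members fell and none rose, or 5 lower and 1 higher adjusted over the list alone. UGT2B17, UGT2B11 and UGT2B15 were 5.20-fold, 4.99-fold and 4.63-fold lower, with the limit on near-identical genes given above, and AKR1C2 fell by 1.14. The adjusted p of this list was 0.000816, and 0.0867 with an estimated correlation. In the mesenchymal list 5 of 12 members were lower and 0 higher, or 5 lower and 1 higher adjusted over the list alone. The fibronectin receptor subunit ITGA5 fell by 1.43 (SE 0.11), CDH2 by 1.12 (SE 0.10) and TNC by 1.00 (SE 0.12). That list had an adjusted p of 0.0151, 0.147 with an estimated correlation, 0.0598 without parental replicate 2 and 0.151 without the background filter.

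The joint list of unfolded protein and amino acid stress genes was higher in the metastatic lines. Of 19 members, 10 rose and 1 fell, or 11 and 1 adjusted over the list alone. PHGDH, which catalyses the entry step of serine synthesis, rose by 0.66 (SE 0.12), and the transcription factor CEBPB by 0.63 (SE 0.11). CHAC1, which degrades glutathione, was at least 1.23-fold higher and was not above background in parental cells. ATF4 rose by 0.47, asparagine synthetase (ASNS) by 0.52, PSAT1 by 0.53 and TRIB3 by 0.51. The member that fell was HSPA5, the main chaperone of the endoplasmic reticulum, with a log2 difference of -0.59. Since the list joins both responses, its call does not show that the unfolded protein part rose. The list's adjusted p was 0.000197, and 0.0867 with an estimated correlation.

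Antigen presentation genes were also higher than in parental cells, with 4 of 13 members higher and none lower, or 6 higher adjusted over the list alone. HLA-C rose by 0.55 (SE 0.10), HLA-E by 0.47 (SE 0.12) and HLA-B by 0.44 (SE 0.13). The adjusted p was 0.00596, 0.147 with an estimated correlation, 0.0580 without parental replicate 2 and 0.0889 among genes with a mean intensity above 7. Class I HLA genes are similar in sequence, and HLA-B and HLA-C lay close to background in parental cells. In cholesterol synthesis 3 of 18 members fell and none rose, or 6 lower adjusted over the list alone. LSS fell by 1.12 (SE 0.13), HMGCS1 by 0.85 (SE 0.14) and INSIG1 by 0.41, while SC5D had a log2 difference of -0.45 and did not pass (adjusted p = 0.0518). SC5D passed in 4 of 18 other settings (0.00174 to 0.390), among them without parental replicate 1, where it fell by 0.72. The adjusted p of the list was 0.000530, and 0.0867 with an estimated correlation. In the WNT list 4 of 13 members were lower and 1 higher, or 5 and 1 adjusted over the list alone. The receptor gene FZD8 fell by 1.10 (SE 0.12), the secreted inhibitor DKK1 by 0.44 (SE 0.12) and AXIN2, a target of the pathway, by 0.42 (SE 0.11), while FZD4 rose by 0.72. This list had an adjusted p of 0.0366, and an adjusted p of 0.173 with an estimated correlation. Its call ended in 4 of 17 other settings (0.0280 to 0.143): without parental replicate 2 (0.143), without M3-1 replicate 1 (0.0519), with array weights (0.0574) and above a mean intensity of 7 (0.0889).

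The fibroblast and smooth muscle list, fixed as markers of other cells, was called upward with 3 of 6 measured members higher and none lower, the same count as adjusted over the list alone (adjusted p = 0.0366, and 0.173 with an estimated correlation). Besides LUM, DCN was at least 1.28-fold higher and TAGLN 1.43-fold higher. The list's adjusted p was 0.0931 without parental replicate 2, 0.0692 without M3-2 replicate 2 and 0.114 without the background filter. The collagen genes of fibroblasts did not follow: COL1A1 had mean log2 intensities of 6.81 in parental cells, 6.95 in M3-1 and 6.73 in M3-2, and COL1A2 and COL3A1 were not above background. Calls of HLA-E, HLA-B, DKK1, AXIN2 and TAGLN ended when single arrays were left out, at the most with an adjusted p of 0.180 for HLA-B without parental replicate 2. With array weights HLA-E (0.0716), HLA-B (0.0982), DKK1 (0.0909) and AXIN2 (0.0915) also lost their calls, as did DKK1 with the mean of its probes (0.164).

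The metastatic lines were next compared with the primary tumour derivative. A difference here can come from the metastatic lines or from the primary tumour alone. KCNJ8, a potassium channel subunit gene, was 9.82-fold higher in the metastatic lines, at 10.43 ± 0.11 (n = 4) against 7.13 ± 0.13 (n = 2). LUM was 8.59-fold higher and LGALS4 6.27-fold higher. EFEMP1 was at least 14.7-fold lower, at 10.43 ± 0.02 (n = 2) in the primary tumour and not above background on any metastatic array (adjusted p = 9.64e-11). FABP7, which had risen in the primary tumour, was 7.07-fold lower in the metastatic lines, with a mean of 6.58 in M3-1 and 8.07 in M3-2.

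WIF1, a secreted WNT inhibitor, was 4.99-fold higher in the metastatic lines than in the primary tumour, IER5L 4.96-fold, SPOCK2 4.63-fold, the protease inhibitor gene A2M 4.61-fold and CALCA, which encodes calcitonin and a related peptide, 4.41-fold. BASP1 was 8.65-fold lower. CNTNAP2, a member of the neurexin family, was at least 6.39-fold lower, FOXA3 at least 5.69-fold and the gap junction gene GJA1 at least 5.49-fold, with CNTNAP2 below background in M3-2 and the others in M3-1. RASL11B was at least 6.06-fold and the homeobox gene IRX4 at least 4.22-fold lower. The highest adjusted p among these was 6.36e-07, that of GJA1. FOXA3 and RASL11B had risen in the primary tumour. Their means in the metastatic lines, 6.55 and 6.22, lay near those of parental cells, 6.56 and 6.28. All of these means were near or below the background level of 6.55, so they do not show a return to the parental level. In total 1443 genes changed, 654 higher and 789 lower, with 168 changed at least 2-fold. Of these 1443, 635 were called in the same direction in each metastatic line. The count was 590 and 652 without primary tumour replicates 1 and 2, and 807 and 837 without M3-1 replicates 1 and 2. It was 2180 without either parental array or with only the arrays compared, and 2257 with array weights, since each of these gives the wide parental spread less part in the error.

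The unfolded protein and amino acid stress list was higher in the metastatic lines than in the primary tumour as well, with 9 of 19 members higher and 1 lower, or 12 and 2 adjusted over the list alone. SLC7A11, a cystine transporter, was at least 1.33-fold higher, ASNS rose by 0.61 (SE 0.12) and ATF4 by 0.53 (SE 0.11). Camera gave an adjusted p of 0.00358, and an adjusted p of 0.167 with an estimated correlation. This call, too, is for the joint list and not for each response. Interferon response genes were higher, with 6 of 21 members higher and 1 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.00879, and 0.167 with an estimated correlation). BST2 rose by 1.35 (SE 0.12), OAS3 by 0.68 (SE 0.12) and MX1 by 0.56 (SE 0.12), while IRF7 fell by 0.54. Antigen presentation genes were higher in 4 of 13 cases and lower in none, or 7 higher adjusted over the list alone (adjusted p = 0.00440, and 0.167 with an estimated correlation). TAP2 rose by 0.64 (SE 0.13), HLA-B by 0.59 (SE 0.13), and PSMB8 was at least 1.14-fold higher, being below background in the primary tumour and on 2 of the 4 metastatic arrays. The antigen presentation list was not called above a mean intensity of 7 (adjusted p = 0.157).

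Androgen response genes were lower in the metastatic lines than in the primary tumour. Of 21 members, 9 fell and 2 rose, or 10 and 5 adjusted over the list alone. ZBTB16 fell by 1.66 (SE 0.14), PMEPA1 by 1.32 (SE 0.13), and the protease gene TMPRSS2 by 0.94 (SE 0.13), and FKBP5 fell by 0.83, while ELL2 rose by 0.95 and TSC22D3 by 0.53. The adjusted p was 0.0291, 0.174 with an estimated correlation, and 0.0577 without primary tumour replicate 2. Hypoxia and glycolysis genes were lower in 7 of 23 cases and higher in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.00440, and 0.189 with an estimated correlation). ANGPTL4 fell by 2.05 (SE 0.14), BNIP3 by 0.93 (SE 0.12) and NDRG1 by 0.79 (SE 0.13), while DDIT4 rose by 0.85. In fatty acid synthesis and lipid storage 6 of 17 members fell and 2 rose, or 9 and 3 adjusted over the list alone (adjusted p = 0.00919, and 0.167 with an estimated correlation). FASN, the fatty acid synthase, fell by 0.98 (SE 0.11), SCD by 0.68 (SE 0.10) and PLIN2, a lipid droplet coat protein gene, by 0.67 (SE 0.11), whereas ACSL1 rose by 1.12. Without primary tumour replicate 2 this list also had an adjusted p of 0.0577.

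The neuroendocrine list was lower again, with 5 of 16 members lower and none higher, or 7 lower adjusted over the list alone (adjusted p = 0.0170, and 0.174 with an estimated correlation). TUBB3 fell by 1.15 (SE 0.14), CHGB was at least 1.43-fold lower, and CELF3 had a log2 difference of -0.42 that did not pass (adjusted p = 0.0503) but passed in 8 of 18 other settings (0.0123 to 0.402). The list was not called above a mean intensity of 7 (0.0605). The TGF-beta and BMP list was higher than in the primary tumour, with 4 of 14 members higher and none lower, or 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.0405, and 0.189 with an estimated correlation). Against parental cells the list had a median of -0.139 in the metastatic lines and was not called by camera (adjusted p = 0.0721). BAMBI, a decoy receptor, rose over the primary tumour by 0.99 (SE 0.12), GDF15 by 0.95 (SE 0.12) and BMP2 by 0.60 (SE 0.11). This call ended in 4 of 17 other settings (0.0274 to 0.150), among them without primary tumour replicate 2 (0.0577) and without M3-2 replicate 1 (0.0825). The p53 list, with a median of -0.033 in the metastatic lines against parental cells, was called upward against the primary tumour. There 1 of 16 members, BBC3, rose by 0.44 (SE 0.11), with the same count adjusted over the list alone. SESN2 and ZMAT3 differed by 0.34 and 0.33 without passing (adjusted p of the list = 0.0321, and 0.174 with an estimated correlation). The list's call ended in 3 of 17 other settings (0.00744 to 0.101), the highest without primary tumour replicate 2. SESN2 passed in 6 of 17 settings (0.0266 to 0.463) and ZMAT3 in 1 of 18, without M3-2 replicate 2 (0.0151 to 0.931). Calls of CHGB, OAS3, MX1, TAP2, HLA-B, PSMB8, ASNS, ATF4, BMP2 and BBC3 ended when single arrays were left out, at the most with an adjusted p of 0.200 for PSMB8 without primary tumour replicate 1.

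**Figure D3:**
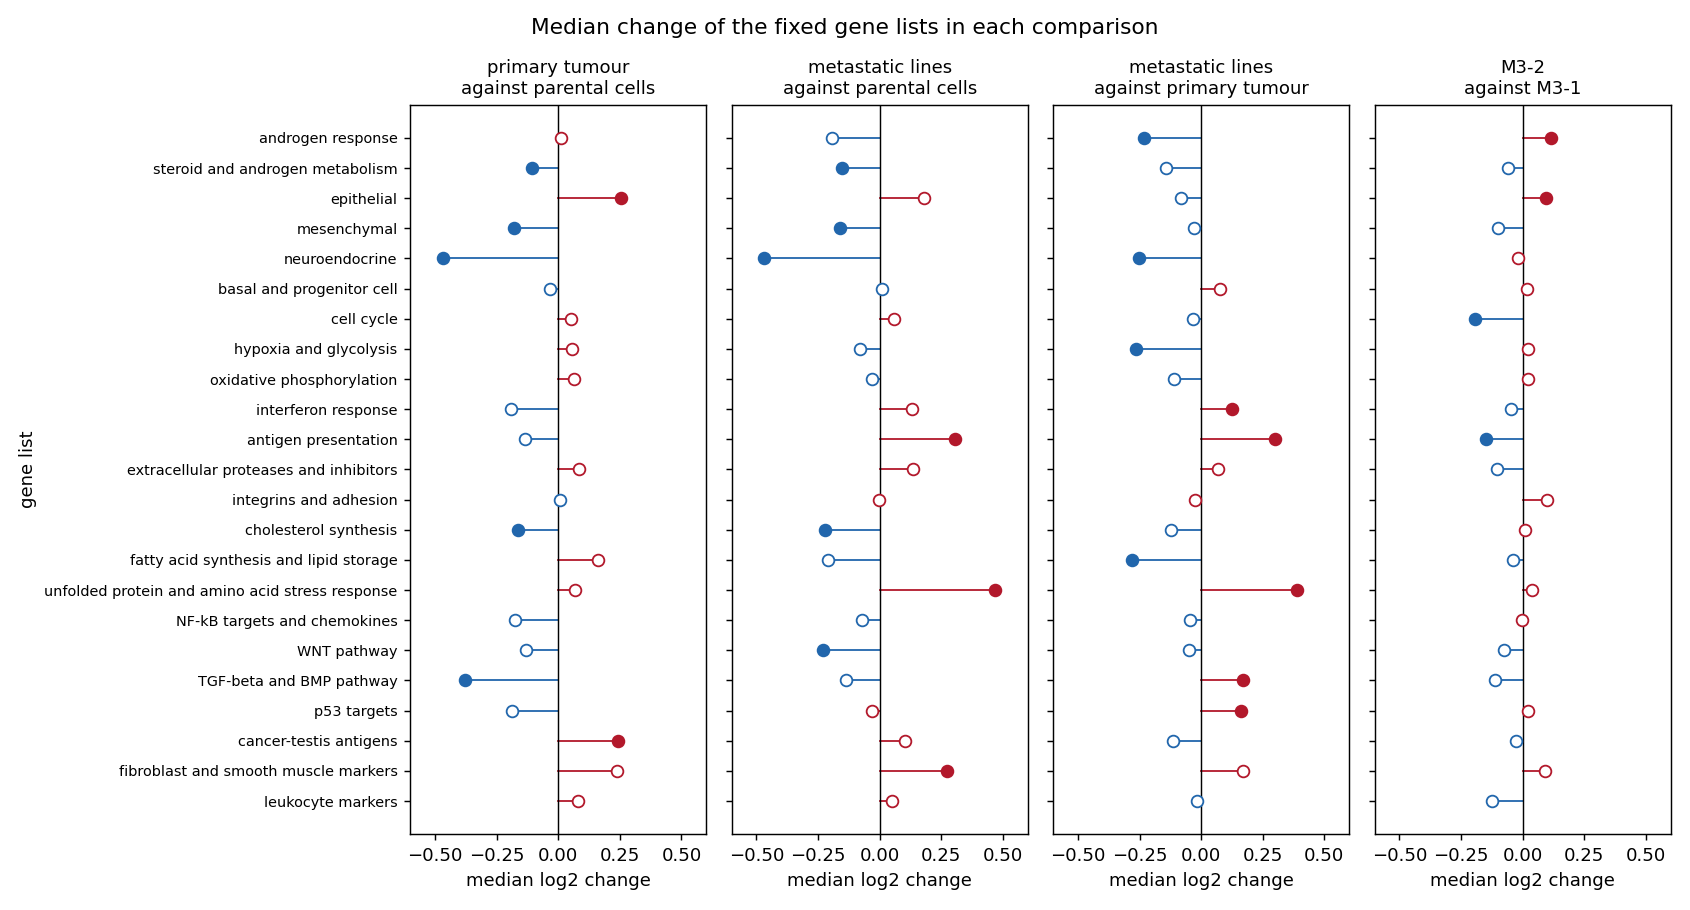
Median log2 change of the measured members of each of 23 gene lists (horizontal axis) in the 4 comparisons. Filled points are lists called by camera at the preset correlation, red upward and blue downward; the neuroendocrine list had medians of -0.47 in both comparisons with parental cells, and the unfolded protein and amino acid stress list had a median of 0.47 in the metastatic lines against parental cells.

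A set of 333 genes separated both metastatic lines from both parental cells and the primary tumour in the same direction, 145 higher and 188 lower. Simulated unchanged groups gave 0, but few genes were called in them at all, so this does not measure the part of shared controls. Of the 333 genes, 56 differed at least 2-fold in all 4 comparisons, and more of them were higher (33) than lower (23). The genes with the largest mean increases were LUM, LGALS4, SPOCK2, KCNJ8, NQO1, P2RY1, IER5L and WIF1. NQO1 was 19.9-fold higher in M3-1 and 20.5-fold higher in M3-2 than in parental cells, and 2.63-fold and 2.72-fold higher than in the primary tumour. KCNJ8 was 5.93-fold and 6.49-fold higher in M3-1 and M3-2 than in parental cells. The largest mean decreases were in EFEMP1, NMB, CNTNAP2, ANGPTL4, GJA1, BASP1, the co-chaperone gene DNAJA4 and HBA2. NMB was 8.95-fold lower in M3-1 and 8.76-fold lower in M3-2 than in parental cells, and DNAJA4 was at least 4.29-fold lower in each. The set held 184 and 187 genes without primary tumour replicates 1 and 2, 166 and 164 without M3-1 replicates 1 and 2, and 218 without M3-2 replicate 1.

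The metastatic lines were compared with each other to see how far they had diverged. CEACAM6, a cell adhesion glycoprotein of mucosal epithelia, was 11.9-fold higher in M3-2, at 11.33 ± 0.10 (n = 2) against 7.76 ± 0.14 (n = 2) in M3-1 (adjusted p = 9.90e-09). LPIN2, a phosphatidate phosphatase, was 10.1-fold higher. ELF5, an epithelial transcription factor, was at least 7.03-fold lower in M3-2, and MAGEC2, a cancer-testis antigen, 4.08-fold lower. Other genes higher in M3-2 were C10orf95 (at least 5.70-fold), the transporter gene SLC68A1 (5.80-fold), monoamine oxidase A (MAOA, 5.55-fold), the kallikrein gene KLK11 (4.91-fold), REG4, a secreted lectin of the gut (4.85-fold), and the chloride channel gene BEST2 (4.68-fold). Lower in M3-2 were the homeobox gene MSX1 (3.26-fold), the tubulin gene TUBB2B (3.05-fold), CALCA (log2 difference -1.58), the glycoprotein hormone subunit CGA (2.88-fold), RTN1 (2.67-fold) and SLC43A3 (2.38-fold). In total 303 genes differed, 174 higher and 129 lower in M3-2, and 74 differed at least 2-fold. The count was 100 and 94 without M3-1 replicates 1 and 2 and 136 without M3-2 replicate 1. It was 492 without either parental array, 484 with only the arrays compared and 548 with array weights.

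Androgen response genes were higher in M3-2 than in M3-1, with 3 of 21 members higher and none lower, or 6 higher adjusted over the list alone (adjusted p = 0.00227, and 0.173 with an estimated correlation). These were SLC45A3 (2.23-fold), ZBTB16 (1.95-fold) and PMEPA1 (1.62-fold). In the epithelial list KRT19 was 2.63-fold, KRT8 1.64-fold and the transcription factor ELF3 1.55-fold higher, so that 3 of 21 members were higher and none lower, or 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00254, and 0.255 with an estimated correlation). Cell cycle genes were lower in M3-2, although KIF20A was the only one of 28 members to pass, with a log2 difference of -0.65 (SE 0.13), and 5 were lower adjusted over the list alone (adjusted p = 0.00254, and 0.173 with an estimated correlation). CDC20 and MKI67 had differences of -0.58 and -0.51 and did not pass in the fit to all arrays (adjusted p = 0.0862 and 0.0679), whose error includes the wide parental spread. CDC20 passed in 6 of 18 other settings (0.00781 to 0.626) and MKI67 in 5 (0.0150 to 0.533). Both passed with array weights, with a replicate block, with only the groups compared (0.0131 and 0.0261) and without either parental array (0.00798 and 0.0256). Antigen presentation genes were lower, with 1 of 13 members passing, PSMB9, which was at least 1.33-fold lower and below background in M3-2, and 4 lower adjusted over the list alone (adjusted p = 0.00376, and 0.207 with an estimated correlation), while TAP1 had a difference of -0.48 without passing, and PSMB8, also below background in M3-2, did not pass either. PSMB8 passed in 6 of 17 other settings (0.0358 to 0.881), among them without either parental array (0.0432), and TAP1 in 1 of 18 (0.0445 to 0.992). This list was not called above a mean intensity of 7 (0.299). Calls of CGA, ZBTB16, PMEPA1, KRT8, ELF3, KIF20A and PSMB9 ended when single arrays were left out, at the most with an adjusted p of 0.491 for PSMB9 without M3-1 replicate 2. PMEPA1 also lost its call with the mean of its probes (0.224).

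E-cadherin (CDH1), vimentin (VIM) and the proliferation marker MKI67 did not pass in any of the 4 comparisons in the fit to all arrays, and MKI67 passed between the metastatic lines in the other settings given above. CDH1 had mean log2 intensities of 11.86 in parental cells, 11.75 in the primary tumour, 11.64 in M3-1 and 11.69 in M3-2, and VIM lay between 9.16 and 9.41. MKI67 was at 8.28 in parental cells, 8.26 in the primary tumour, 8.71 in M3-1 and 8.19 in M3-2. KLK3, which encodes prostate-specific antigen, was not above background, with group means between 6.12 and 6.32.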

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

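The metastatic lines differed from each other in 303 genes, by the test of M3-2 against M3-1. Among the 79 genes named in the metastatic comparisons, 16 differed between the lines, 11 higher and 5 lower in M3-2. The largest difference was in BASP1, a membrane protein gene that was lower than in the primary tumour in both lines but by less in M3-2, where it was higher by 2.11 on the log2 scale. The genes that rose in both lines but further in M3-2 were WIF1 (1.55), SPOCK2 (1.46), LGALS4 (1.20) and PPP1R1B (1.11). HBA2 (1.52), IGFBP3 (1.21) and CHGB (0.80) were lower than in parental cells in both lines, and less so in M3-2, with CHGB below background in M3-1 and so at least 1.61-fold higher in M3-2. FABP7 (1.49), ZBTB16 (0.96) and PMEPA1 (0.70) were also higher in M3-2. Lower in M3-2 than in M3-1 were CALCA (-1.58), ADA2 (-0.97), BST2 (-0.91), BMP2 (-0.84) and UGT2B17 (-0.65). Each line is 1 derivative, so these differences were not tested against the spread between independent metastases, and no explanation for the differences of the 16 named genes was tested.

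Probes without a single gene symbol also carried signal. Of 5655 such probes above background, 235 changed between the metastatic lines and parental cells by the same test, 100 higher and 135 lower. They entered no comparison of genes.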

How the results depend on the processing

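Named genes were recomputed under 18 alternatives, counts also at stricter thresholds, and lists also with other set tests. Normexp background correction, cyclic loess and a mean intensity above 7 were chosen after seeing the data, as was the split of the parental arrays. No called list or called named gene reversed direction; uncalled differences near 0 of CDH1, VIM and MKI67 did in some settings. The balance of the primary tumour against parental cells, 420 higher and 425 lower, turned in several settings (440 and 436 without the filter, 344 and 308 above intensity 7), and that of M3-2 without M3-2 replicate 2 (561 and 554). At 2-fold or more, the balance of the genes shared by both lines against both groups also turned, from 145 higher and 188 lower to 33 and 23. Normexp, cyclic loess and the intensity filter left all counts within 1.5 times. Both normexp and cyclic loess were applied to the deposited values, whose arrays already shared the same distribution. Cyclic loess could therefore change little, and neither shows how the counts depend on the authors' own normalization. Counts are given for the primary tumour, both metastatic lines, M3-1 and M3-2 against parental cells, the metastatic lines against the primary tumour, M3-2 against M3-1, and the genes shared by both lines against both groups, in this order. At least 2-fold changes numbered 164, 299, 292, 365, 168, 74 and 56. With adjusted p below 0.01 the counts were 428, 998, 733, 908, 750, 164 and 179. Leaving out 1 array at a time gave ranges of 354 to 1395, 1099 to 2064, 572 to 1599, 927 to 1999, 590 to 2180, 94 to 492 and 164 to 470. The lone array left in a group was assumed to vary like the other groups. Array weights gave 1089 for the metastatic lines against parental cells, 2257 against the primary tumour and 548 between the lines. With only the groups compared, the primary tumour gave 419, M3-2 gave 994 against parental cells, the metastatic lines gave 2180 against the primary tumour, and M3-2 gave 484 against M3-1. Parental arrays had the lowest weight, 0.466, which lowers counts against parental cells and raises the others. Of 92 list results, all 28 calls were lost with an estimated correlation. Apart from that, 14 of the 28 held in all other camera settings and 14 ended in at least 1, while 8 of 64 uncalled lists were called in at least 1. Fry, which asks only whether a list changed at all, passed 24 lists that camera did not. Of 134 calls of named genes, 108 held in all settings and 26 ended in at least 1, while 11 of 23 uncalled ones passed in at least 1.

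By the labels, arrays of different groups share only a replicate number. Correlations of the replicate differences were 0.52 between parental cells and the primary tumour and between -0.18 and 0.17 for the other pairs of groups. The differences between replicates were thus partly common to parental cells and the primary tumour. The main fit leaves this out, and its source was not tested. A replicate block gave 1143, 1955, 1434, 1738, 1784, 389 and 400 genes, the first being the primary tumour against parental cells, with 845 in the main fit. Planned neqc correction, detection p-value filters, quantile normalization of raw signals and normexp with median scaling were not run, since the signals without normalization were not used here. Dim genes are limited by the background: the floor was 5.32 and the detection level 6.55, so their folds are lower than without background.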

Other observations

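Some genes of the fixed lists moved strongly in lists that were not called as a whole, and are named here after their values were seen. In the androgen response list, for the metastatic lines against parental cells, 8 of 21 members fell and 3 rose, or 9 and 4 adjusted over the list alone, without the list passing (adjusted p = 0.0721). PMEPA1 fell by 1.79, FKBP5, a co-chaperone of steroid receptors, fell by 0.93 and TMPRSS2 fell by 0.93. The glucocorticoid-induced gene TSC22D3 rose by 2.39 and FOLH1, which encodes prostate-specific membrane antigen, by 1.16. The list holds its members without the direction in which androgens move each of them. Neither the rises nor the falls alone therefore show a higher or lower response. ACSL1, an acyl-CoA synthetase, rose by 2.31, and MAGEC2, which was below background in parental cells, was at least 3.8-fold higher.

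The fibroblast and smooth muscle markers below are a list fixed before the data were examined, and their use for LUM was chosen after its rise was seen. The NRF2 and gut-type lists were chosen after the largest changes had been seen, but before the values of their own members were seen. Some of their members, among them SLC7A11, ME1 and CEACAM5, also stand in the fixed lists. LUM rose in both metastatic lines. Lumican is made by fibroblasts, so host stroma was tested as a source, through the 16 other fibroblast and smooth muscle markers on the array. Their median change was 0.0165 (SE 0.0366), and 0 of them rose by 1 or more. The SE of a median, here and below, comes from the spread between the genes of a list, taken as independent, not between arrays. However, only 6 of the list's 17 markers, LUM among them, were above background, and small changes of the others would not show. Of the measured others, DCN rose by at least 0.36 and TAGLN by 0.52. COL1A1, FBLN1 and ACTA2 differed by 0.03, -0.14 and -0.19 without passing. No other marker rose as LUM did, but the test cannot exclude a smaller signal from stromal transcripts. A fault of 1 probe is argued against by the other LUM probe, which rose by 3.47, or by at least 3.10 counted from the background level, since it was below that level in parental cells. Mouse lumican binding these human probes specifically was not tested and stays open, as does a rise within the tumour cells.

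NQO1 is a target of the oxidative stress regulator NRF2, so a general rise of NRF2 targets was tested in 15 measured members of a list of 20. Their median change in the metastatic lines was 0.21 (SE 0.16), between the bounds of 0.25 and 0.1 set for the test. GPX2, ME1, EPHX1 and UGDH rose, by 1.13, 0.96, 0.95 and 0.52, SLC7A11 was at least 1.33-fold higher from below background, GCLC fell by 0.96 and FTL fell by 0.53, and 8 did not pass. The set test gave p = 0.0287, and p = 0.0798 with an estimated correlation, so the test left the explanation open. A fault of 1 probe is argued against by the other NQO1 probe, which rose by 3.22, or by at least 3.07 counted from the background level.

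CEACAM6 and REG4, genes of mucosal secretory cells, were higher in M3-2 than in M3-1, and a broader gut-type secretory programme was tested as a hypothesis in 15 measured members of a list of 35. Their median difference was 0.038 (SE 0.138). ZG16, ATOH1 and CEACAM5 were below background in M3-1 and higher in M3-2 by at least 1.13, 0.76 and 0.58 on the log2 scale, TFF2 was lower at -0.85, and 11 did not pass. The set test pointed upward with p = 0.0157, and p = 0.0851 with an estimated correlation. The median lay below the bound of 0.1 set beforehand as evidence against the hypothesis, but by less than its standard error between genes. Weighing the median against its error was added after the value was seen; without it, the test would count against a broader programme. With members moving both ways, the test was taken as undecided.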
